A study of Xenopus laevis with 3 samples.

How the data were processed

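Per the labels, neuronal tissue of the accessory olfactory bulb was cut from frozen sections (50 µm) of Xenopus laevis larvae at stage 45, 15 days old, raised in orphan, sibling or non-sibling conditions. The labels name 15 larvae without saying whether that number is per condition or in all, and they give no details of the rearing. Total RNA was extracted with the RecoverAll kit, per the labels, and samples with degraded RNA were excluded by the submitters. The protocol names a preparation kit for messenger RNA, whereas the labels describe the molecules as microRNA and the series as profiling of non-coding RNA, so the library method for these counts is not settled. The 3 libraries, 1 per condition, were each taken as their own group from their titles.

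The deposited table gives, per mature microRNA entry, a read count for each library, per the file headers, as whole numbers with no normalization. It also gives a signal made by the authors from these counts, namely quantile-normalized counts, for which the 3 libraries share 1 distribution. In addition it gives the log2 ratio of quantile-normalized counts between each pair of libraries, as deposited by the authors. The offset added before the logarithm is not stated, and testing on the values gave an offset of 102.333, the median of the quantile-normalized orphan column, with a largest deviation of 4.14e-05. The aligner, the counting tool, the microRNA release and any genome build are not given in the sources used here. The table holds 1272 named entries with 1144 distinct mature sequences under 80 species prefixes, and 178 of them are Xenopus entries (166 X. tropicalis, 9 X. laevis and 3 X. borealis). Identical or near-identical sequences of several species share many reads, so a column total counts reads more than once and is a relative depth only. Their counts can still differ: fru-miR-375 and xtr-miR-375 have 1 sequence but 30674 and 28709 counts in the orphan library. Reads of close paralogs cannot be told apart in these counts. The 1 unnamed line, which holds a median of the normalized values, was left out. No genome positions are given, since no genome was used here.

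With 1 library per condition there is no test between conditions. The main result for each pair of libraries was the ratio of scaled counts with its exact conditional 95% interval (Clopper-Pearson interval of the share of counts in 1 of both libraries), which compares libraries and covers counting error only. Counts were scaled by effective library sizes from trimmed means of M values (TMM, edgeR 4.0.16 in R 4.3.3) over all 3 libraries, with factors 0.965 for orphan, 0.817 for sibling and 1.27 for non-sibling. An entry was used with a sum of at least 30 counts over the 3 libraries, which 866 entries had. An entry counted as higher or lower with a ratio of at least 2, or at most 0.5, and an interval that excluded 1. Log2 ratios have 0.5 added to each count. A ratio against 0 counts is a bound against a floor of 3 counts per library. That floor was 0.138 scaled CPM in the orphan, 4.24 in the sibling and 0.456 in the non-sibling library. Of the 1272 entries, 46 had no count in the orphan library, 340 in the sibling library and 205 in the non-sibling library. The other statistics were computed in Python 3.11.15 with numpy 2.4.6, pandas 2.3.3 and scipy 1.17.1, and plots were drawn with matplotlib 3.10.9.

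The groups, the size rule, the filter, the 18 microRNA lists, the rule for named microRNAs and a first set of alternatives were fixed before the data were examined. The named microRNAs were the 10 entries with the largest ratio in each direction for each comparison with sibling, and the 5 largest in each direction for orphan against non-sibling. Each needed a sum of at least 150 counts and had to pass the size rule, and of entries with 1 name in several species the entry with the most counts was named. In addition the rule took the entries of miR-200b and miR-375, the 10 most abundant entries by counts pooled over the libraries, and up to 4 members of each list with the most counts. The lists covered the followed-up microRNAs, the miR-200 family, dopaminergic neurons, neurons, activity-regulated microRNAs, sensory organs, skin epithelium, let-7, miR-17-92 and its paralogs, the early embryo, erythrocytes, leukocytes, muscle, vascular cells, mesenchyme and cartilage, oligodendrocytes, digestive organs and the Hox clusters. For each list the median log2 ratio was set against 10000 random lists of the same size, matched on mean abundance in 10 bins. The percentile describes these libraries and is no p-value, and entries that share reads make a list look more uniform than independent microRNAs would, so it is also given for Xenopus entries alone. For those, identical and contained sequences were merged and TMM factors were computed again. The shared sibling library was treated by 100 simulations of Poisson counts with no difference between libraries.

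The calculation was tested on independent Poisson counts for the 866 entries, drawn from the real depths, with 200 entries changed by known folds in orphan. These folds raised the simulated orphan total to 26696384 counts, against 22536558 real counts in these entries. Reads shared between entries were not simulated. For orphan against sibling, 94% of entries changed 4-fold upward, 84% at 2.5-fold, 70% at a fold of 0.4 and 94% at 0.25 were recovered, and 7 of 666 unchanged entries passed the rule. For orphan against non-sibling, 100% at 4-fold, 96% at 2.5-fold, 88% at 0.4 and 100% at 0.25 were recovered, with 2 of 666 unchanged entries passing. For non-sibling against sibling, where nothing was changed, 8 of 866 entries passed. The intervals held the true ratio for 96.0%, 95.5% and 95.7% of entries in these 3 comparisons.

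That first set held scaling by total counts, by DESeq2 1.42.0 size factors and by upper quartiles, leaving out the most abundant entry, no filter, a sum of at least 150 counts, summing entries of 1 name, ratio thresholds of 1.5 and 4, an interval wholly beyond 2-fold, 5 counts in place of 0.5, and family sums. Chosen after seeing the data were Xenopus entries alone, leaving out families with no Xenopus entry, thinning to the sibling total (20 draws), the authors' quantile normalization, removal of a trend on GC content and length, and TMM without the sibling library. Plant and viral entries were left out by the count filter and entered only the alternative without a filter.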

Results

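Small RNA was counted in neuronal tissue of the accessory olfactory bulb, the forebrain relay of the vomeronasal system, from Xenopus laevis larvae at stage 45, 15 days old. The larvae came from 3 rearing conditions, named orphan, sibling and non-sibling, with 1 library each (n = 1 per condition). The series title places the data in a study of microRNA control of a switch in neurotransmitter use that affects social preference. The comparisons ask which microRNAs differed between the rearing conditions. No difference given here has a replicate check, no p-value can be given, and each describes these libraries, not the conditions. All intervals and floors cover counting error only, because amplified reads without molecular identifiers are not independent molecules.

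The total count was 22538325 in the orphan library, 865654 in the sibling library and 5188106 in the non-sibling library. The orphan library was thus 26.0 times, and the non-sibling library 5.99 times, as deep as the sibling library. A single count stood for 0.0460, 1.41 and 0.152 scaled CPM in the orphan, sibling and non-sibling libraries, so that the sibling library limited what could be detected. The table listed 1272 mature microRNA entries under 80 species prefixes, and reads of a conserved microRNA were listed under several near-identical entries. Counts of entries therefore weigh conserved families more than once, and values for the 153 distinct Xenopus sequences (prefixes xtr for X. tropicalis, xla and xbo) are given beside them. No genome positions were analysed here.

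By counts pooled over the 3 libraries, a ranking set mostly by the deep orphan library, the most abundant entry was miR-182, a member of the miR-183 cluster of sensory organs. It held 3.56% of all counts in the orphan library (95% exact binomial interval 3.55 to 3.57%), 1.80% in the sibling library (1.78 to 1.83%) and 2.82% in the non-sibling library (2.81 to 2.83%). It was followed in the pooled counts by miR-181a, miR-183, miR-204, miR-92a and miR-26a. In the sibling library xtr-miR-92b (44582 counts), mmu-miR-6243 (30506) and dre-miR-92a (19501) exceeded miR-182 (15623). Entries of families that have no Xenopus entry in the table took 1.35% of counts in the orphan library, 5.81% (5.76 to 5.86%) in the sibling library and 1.64% in the non-sibling library.

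miR-375, known from endocrine cells and the pancreas, and miR-200b, of an epithelial family that also acts in olfactory neurogenesis, are the microRNAs the study followed up. For xtr-miR-375 (UUUGUUCGUUCGGCUCGCGUUA) the counts were 28709, 806 and 15649 in the orphan, sibling and non-sibling libraries, or 1319, 1140 and 2380 scaled CPM. The non-sibling level was 2.09 times the sibling level (95% counting interval 1.95 to 2.24), the orphan level was 1.16 times the sibling level (1.08 to 1.24), and the orphan level was 0.554 times the non-sibling level (0.544 to 0.565). For xtr-miR-200b (UAAUACUGCCUGGUAAUGAUGAU) the counts were 19141, 558 and 9002, and the same ratios were 1.74 (1.59 to 1.89), 1.11 (1.02 to 1.22) and 0.643 (0.627 to 0.659). Of these 6 ratios, only that of xtr-miR-375 between the non-sibling and sibling libraries reached the 2-fold size set in advance. That held under the main scaling. Under total counts the log2 ratio of orphan over non-sibling was -1.24 for xtr-miR-375 and -1.03 for xtr-miR-200b, and that of non-sibling over sibling was 1.43 for xtr-miR-200b, all past 2-fold. With scaling on Xenopus entries alone xtr-miR-375 was at -1.00 in orphan over non-sibling, at the edge of the rule. With a trend on GC content and length removed, an alternative chosen after seeing the data, xtr-miR-200b was at 0.39 in non-sibling over sibling and turned to -0.41 in orphan over sibling. In the authors' deposited table, which compares quantile-normalized counts, the log2 ratio of non-sibling over sibling was 1.54 for xtr-miR-375 and 0.76 for xtr-miR-200b. The log2 ratio of non-sibling over orphan in the authors' deposited table was 0.97 and 0.64, and that of sibling over orphan was -0.57 and -0.12.

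**Figure D1:**
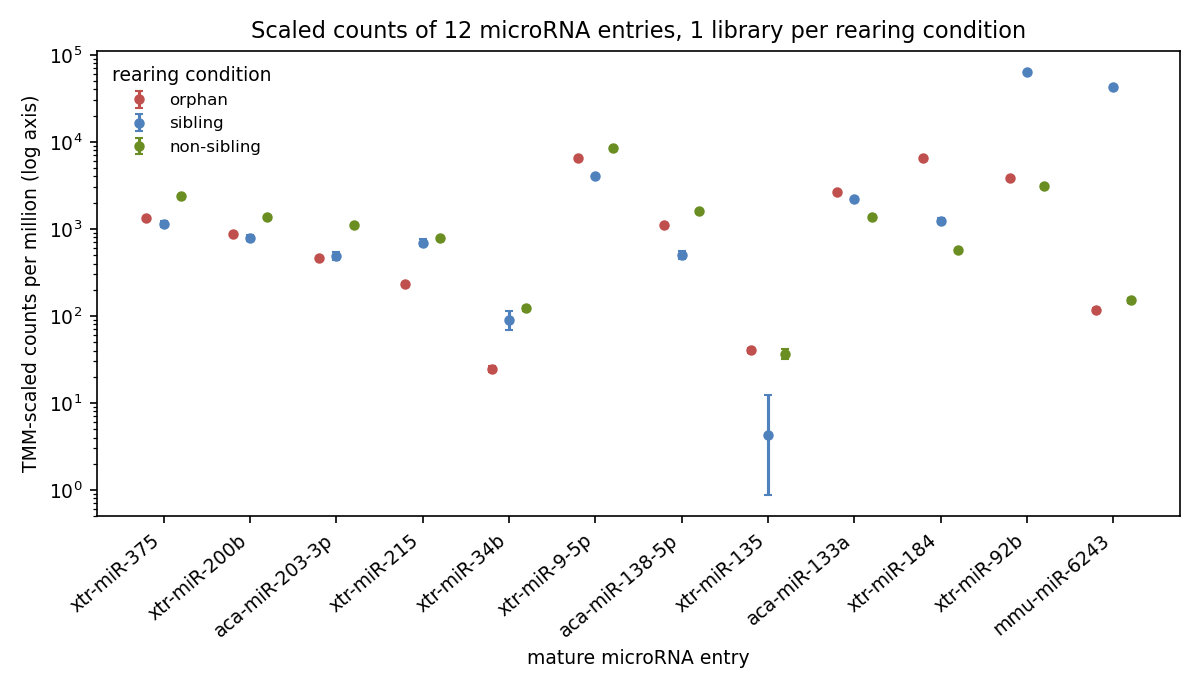
TMM-scaled CPM (log axis) of 12 mature microRNA entries in the orphan, sibling and non-sibling libraries (1 library each), with bars for the exact 95% Poisson interval of the count, most of them smaller than the points. xtr-miR-375 lies at 1319, 1140 and 2380, xtr-miR-184 at 6455, 1246 and 568, and xtr-miR-92b at 3828, 63039 and 3126 in the orphan, sibling and non-sibling libraries.

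The comparison of the orphan with the sibling library asked which microRNAs differed between larvae of the orphan and of the sibling condition. miR-184, xtr-miR-9b-3p, miR-135 and miR-451 were higher in the orphan library, and xtr-miR-92b, 16 of 23 gut entries and 10 of 28 let-7 entries were lower. For xtr-miR-184 (UGGACGGAGAACUGAUAAGGCU), abundant in the epithelia of the eye in vertebrates, 140443 counts in the orphan library stood against 881 in the sibling library, a ratio of 5.18 (4.85 to 5.54). miR-135, on the list of microRNAs known from dopaminergic neurons, was higher by a ratio of 9.47 (3.23 to 46.0), which rests on 3 counts in the sibling library, and its 3 leading entries held nearly the same reads. miR-451, a microRNA of red blood cells, also had 3 counts there and a ratio of 4.24 (1.44 to 20.6). xtr-miR-9b-3p, of a family of neural progenitors and neurons, was 3.30 times as high (2.35 to 4.81), ccr-miR-181c 3.65 times (2.08 to 7.07) and gga-miR-1662 3.41 times (1.95 to 6.62).

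Among the lower entries, xtr-miR-92b (UAUUGCACUCGUCCCGGCCUC), of the miR-25 and miR-92 family of dividing cells, stood at 0.0607 times the sibling level (0.0600 to 0.0614), with 83298 counts in the orphan and 44582 in the sibling library. The entry mmu-miR-6243 was at 0.00272 times the sibling level (0.00261 to 0.00283), sha-miR-716b at 0.00397, mmu-miR-5109 at 0.00404 and hsa-miR-6087 at 0.00392. These 4 names have no Xenopus entry in the table, as have 19 of the 134 lower and 3 of the 77 higher entries, and such entries held 5.81% of the sibling counts against 1.35% of the orphan counts. mmu-miR-6240 (0.0315), bta-miR-1306 (0.0371) and cgr-miR-1260 (0.0647) were also lower.

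Of the 866 entries with enough counts, 77 were higher and 134 lower in the orphan library by at least 2-fold with an interval that excluded 1. Among the 153 Xenopus entries these numbers were 9 and 23. Scaling by total counts gave 121 higher and 118 lower, and the authors' quantile normalization gave 130 and 113, so the balance of directions depended on the scaling. Total-count scaling moved the median log2 ratio of all entries by 0.24, and upper-quartile scaling by 0.16.

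By list, the digestive organ microRNAs (liver, gut and pancreas list) had the lowest median in the orphan library. Of 23 entries 16 were lower, none was higher and 7 were neither, with a median log2 ratio of -1.45. That median lay at percentile 0 among 10000 random lists matched on abundance, as a description of these libraries, and the Xenopus entries alone gave -1.62 and percentile 1.68. xtr-miR-215 was at 0.335 times the sibling level (0.306 to 0.369) and xtr-miR-192 at 0.332 times (0.3004 to 0.368). The let-7 family, which is linked to the end of cell division and to differentiation, had 10 of 28 entries lower and 18 neither, with a median of -0.94 (percentile 0; Xenopus entries -1.13, percentile 0.35). xtr-let-7f was at 0.767 times the sibling level (0.684 to 0.863) and ggo-let-7a at 0.520 times (0.461 to 0.588). The neuronal list divided, with 15 of 96 entries higher, 13 lower and 68 neither. xtr-miR-9-5p (UCUUUGGUUAUCUAGCUGUAUG) was 1.61 times as high (1.55 to 1.67), whereas dre-miR-125a was at 0.205 times (0.201 to 0.209). The neuronal median was 0.36 (percentile 99.99; Xenopus entries percentile 99.75), or -0.14 without a filter on low counts and -0.15 with 5 counts added to each count, and the mean was 0.01. In the activity-regulated list, of microRNAs that follow neuronal activity or act at synapses, 7 of 20 entries were higher and none lower (median 0.36, percentile 97.8; Xenopus entries percentile 99.0), and aca-miR-138-5p was 2.22 times as high (1.997 to 2.47). Of the 3 Xenopus entries of that list 2 passed the size rule, xtr-miR-212 among them on 3 sibling counts. In the dopaminergic neuron list 10 of 37 entries were higher and none lower (median 0.36, percentile 99.1, but -0.06 without a filter). Its Xenopus entries alone lay at percentile 90.8, inside the range of random lists. Of these 4 entries only xtr-miR-135 passed the size rule, on 3 sibling counts. In the same list aca-miR-132-5p was 1.32 times as high (1.15 to 1.53). The neuronal, activity-regulated and dopaminergic medians were 1 value (0.35805), that of shared entries. These lists overlap and are not separate results in any of the comparisons. The erythrocyte list had 3 of 6 entries higher (median 0.98, percentile 99.7, but -3.18 without a filter), all of them miR-451 entries with 3 sibling counts, and 1 Xenopus entry gives no Xenopus percentile. In the list of the followed-up microRNAs none of 19 entries passed the size rule (median -0.06, percentile 17.9). This list was chosen by the study on these libraries and is no independent evidence of a direction.

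**Figure D2:**
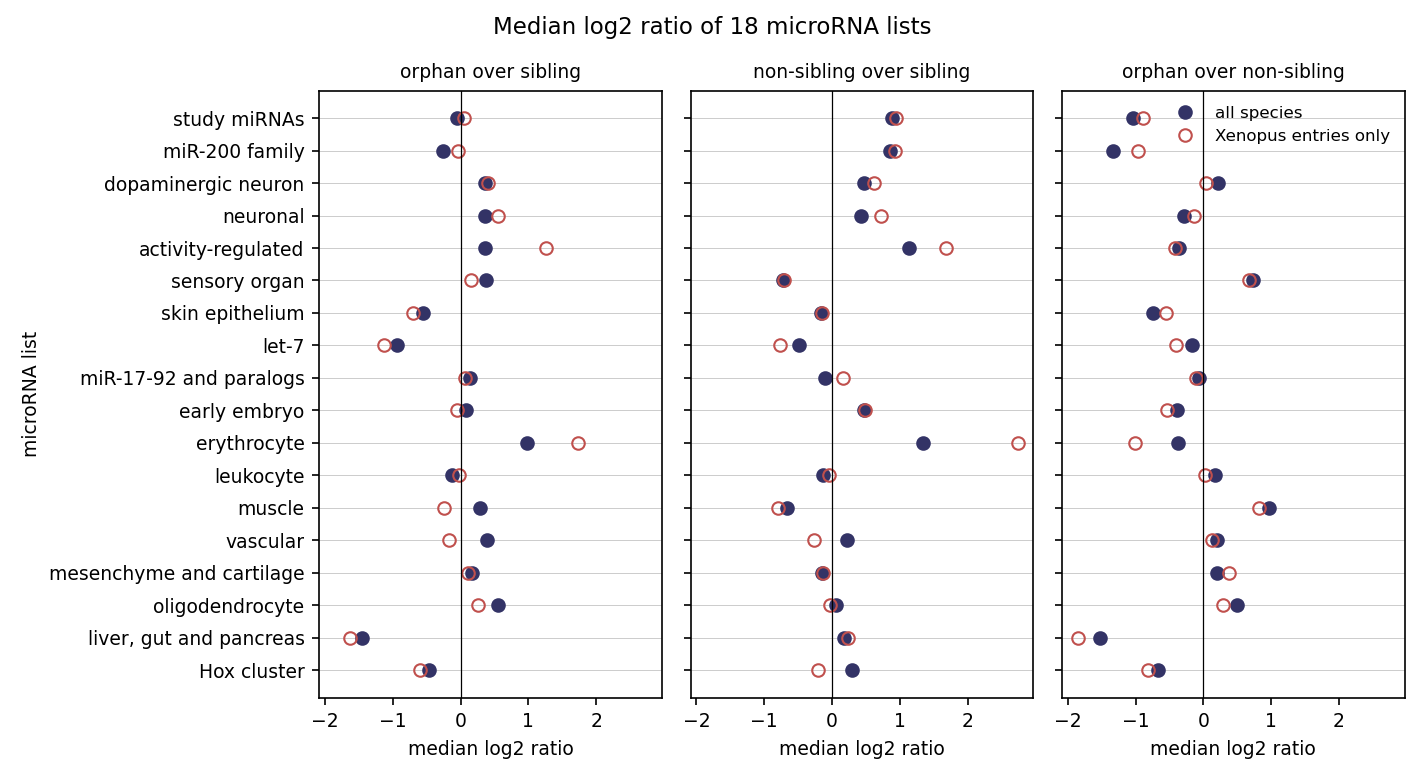
Median log2 ratio of 18 microRNA lists in each pair of libraries, over all entries of a list (filled points) and over its Xenopus entries, 1 to 17 per list (open points), with 1 library per condition. The liver, gut and pancreas list lies at -1.45 in orphan over sibling and at -1.52 in orphan over non-sibling, and the muscle list at 0.96 in orphan over non-sibling.

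The comparison of the non-sibling with the sibling library asked the same of larvae of the non-sibling condition. miR-135, miR-451, miR-23a, miR-138 and 10 of 29 miR-200 family entries were higher in the non-sibling library, and xtr-miR-92b, miR-204, miR-125a and 4 of 49 muscle entries were lower. miR-135 was higher by a ratio of 8.57 (2.90 to 41.8) and miR-451 by 7.67 (2.59 to 37.5), both on 3 counts in the sibling library. gga-miR-22-5p had a ratio of 11.1 with an interval from 1.94 to 442, since the sibling library held 1 count. dre-miR-23a was 4.18 times as high (2.001 to 10.5), xtr-miR-449b-5p, of a family of ciliated cells, 3.76 times (1.44 to 14.0) and miR-155, of activated white blood cells, 3.44 times (1.14 to 17.0). xtr-miR-92b was at 0.0496 times the sibling level (0.0488 to 0.0504), with 20554 counts in the non-sibling library, and bta-miR-365-5p at 0.0465 times (0.0242 to 0.0857). sha-miR-716b (0.00159), mmu-miR-6243 (0.00350) and mmu-miR-5109 (0.00538) were again far lower than in the sibling library.

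In this comparison 97 of 866 entries were higher and 104 lower, and 21 and 14 of the 153 Xenopus entries. Of the 104 lower entries 20 belonged to families without a Xenopus entry, which held 1.64% of the non-sibling and 5.81% of the sibling counts. Scaling by total counts gave 280 higher and 57 lower, with the median log2 ratio of all entries moved by 0.63.

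The miR-200 family had 10 of 29 entries higher, none lower and 19 neither, with a median log2 ratio of 0.86 (percentile 100, and 0.93 at percentile 98.3 for Xenopus entries). This list holds the miR-200b entries, which the study chose on these libraries, so it is only partly independent of that choice. xtr-miR-429 was 1.88 times as high (1.72 to 2.05) and ccr-miR-200a 2.11 times (1.82 to 2.46). The list of the followed-up microRNAs, which the study chose on these libraries and which is thus no independent evidence, had 7 of 19 entries higher and 12 neither (median 0.88, percentile 100). The activity-regulated list had 9 of 20 entries higher and none lower, with a median of 1.14 (percentile 100; Xenopus entries 1.68, percentile 98.5), and aca-miR-138-5p was 3.19 times as high (2.86 to 3.55). Of the 3 Xenopus entries of the activity-regulated list 2 passed the size rule, xtr-miR-212 among them on 3 sibling counts. In the neuronal list 22 of 96 entries were higher and 15 lower (median 0.42, percentile 99.97; Xenopus entries percentile 99.3). xtr-miR-9-5p was 2.08 times as high (2.01 to 2.17), and dre-miR-125a was at 0.159 times the sibling level (0.155 to 0.163). The dopaminergic neuron list had 9 of 37 entries higher and none lower (median 0.48, percentile 98.9). But its Xenopus entries lay inside the range of random lists (percentile 81.2). Of these 4 entries only xtr-miR-135 passed the size rule, on 3 sibling counts. As above, the activity-regulated, neuronal and dopaminergic lists overlap and are not separate results. The erythrocyte list had the same 3 miR-451 entries higher and its other 3 entries just below 0 (median 1.34, percentile 99.55), and its median was -2.88 without a filter and -0.11 with entries of 1 name summed. In the gut list none of 23 entries passed the size rule (median 0.17, percentile 72.2).

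The muscle list had a low median of -0.67 (percentile 0.02; Xenopus entries -0.79, percentile 0.905), although 4 of 49 entries passed the size rule and 45 did not. Its most abundant microRNA, aca-miR-133a, was at 0.629 times the sibling level (0.595 to 0.664). The sensory organ list (miR-96, miR-182 and miR-183) had a median of -0.73 (percentile 1.09; Xenopus entries percentile 18.3), with 2 of 26 entries higher and none lower, and ccr-miR-183 was at 0.604 times (0.590 to 0.618). The let-7 median was -0.48 (percentile 2.63; Xenopus entries percentile 2.35) and became 0.15 at the same percentile under total-count scaling, which shifts all entries alike. In the miR-17-92 list 37 of 87 entries were lower and 3 higher, much as in orphan over sibling, with 34 lower and 5 higher. The list median for non-sibling over sibling was -0.11 (percentile 23.2), or 0.53 at the same percentile under total-count scaling. It differed in size from the mean of -0.74, with the miR-92 entries far below the others. dre-miR-92a was at 0.322 times the sibling level (0.316 to 0.327).

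The orphan and the non-sibling libraries are the deeper pair. miR-184 was the microRNA most in excess in the orphan library, and the miR-34b, miR-34c and miR-449 entries, 17 of 23 gut entries, 20 of 29 miR-200 family entries and 4 of 13 skin entries were lower there. xtr-miR-184 was 11.4 times as high (11.0002 to 11.7), and the other arm of its precursor, ola-miR-184-5p, 5.41 times (2.87 to 11.5) on 179 and 10 counts. aca-miR-19a-3p, of the miR-17-92 cluster, was 4.15 times as high (2.94 to 6.03). xtr-miR-34b was at 0.201 times the non-sibling level (0.179 to 0.224), aca-miR-34c-5p at 0.204 (0.182 to 0.228) and xtr-miR-449a-5p at 0.208 (0.177 to 0.243), all of families known from ciliated cells. hsa-miR-6087, with no Xenopus entry, was at 0.0682 times (0.0353 to 0.123) on 14 and 62 counts.

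In all, 65 of 866 entries were higher and 109 lower in the orphan library, and 7 and 25 of the 153 Xenopus entries. Total-count scaling gave 30 higher and 225 lower, and upper-quartile scaling 100 and 97, with the median log2 ratio of all entries moved by -0.39 and 0.16.

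The gut list had 17 of 23 entries lower and 6 neither, with a median log2 ratio of -1.52 (percentile 0; Xenopus entries -1.86, percentile 0.465), and xtr-miR-215 was at 0.295 times the non-sibling level (0.284 to 0.307). The miR-200 family had 20 of 29 entries lower and 9 neither (median -1.33, percentile 0, and -0.97 at percentile 3.06 for Xenopus entries), ccr-miR-200a at 0.394 times (0.377 to 0.411). This list, too, holds the miR-200b entries that the study chose on these libraries. The followed-up microRNAs, again no independent evidence, had 10 of 19 entries lower and 9 neither (median -1.03, percentile 0). In the skin list 4 of 13 entries were lower and 9 neither (median -0.75, percentile 0.02; Xenopus entries percentile 7.97), with aca-miR-203-3p at 0.423 times (0.410 to 0.436) and ccr-miR-205 at 0.764 times (0.752 to 0.776). The Hox cluster list had 5 of 19 entries lower and 14 neither (median -0.67, percentile 0.915; Xenopus entries percentile 11.1), xtr-miR-10b at 0.849 times (0.797 to 0.903).

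The muscle and sensory organ lists had high medians in the orphan library. In the muscle list 17 of 49 entries were higher, none lower and 32 neither (median 0.96, percentile 100; Xenopus entries 0.81, percentile 99.9), and aca-miR-133a was 1.95 times as high (1.91 to 1.99). In the sensory organ list 5 of 26 entries were higher and 1 lower (median 0.73, percentile 99.98; Xenopus entries percentile 92.6), and ccr-miR-183 was 2.14 times as high (2.12 to 2.16). The dopaminergic neuron list had 3 of 37 entries higher and 3 lower, with a median of 0.22 (percentile 98.7; Xenopus entries percentile 84.3). Total-count scaling, which shifts all entries alike, made that median -0.17 at the same percentile. The neuronal list had 4 of 96 entries higher and 9 lower (median -0.29, percentile 2.675; Xenopus entries percentile 55.2), and the activity-regulated list none of 20 higher and 4 lower (median -0.35, percentile 12.8; Xenopus entries percentile 55.5), opposite in sign to their medians against sibling. The remaining lists of cell types also lay within the range of random lists. The median was 0.17 for leukocytes (percentile 81.5), 0.19 for vascular cells (percentile 95.2) and 0.21 for mesenchyme and cartilage (percentile 71.7), and each of these 3 turned negative under total-count scaling. It was 0.49 for oligodendrocytes (percentile 65.9), -0.37 for erythrocytes (percentile 55.0) and -0.39 for the early embryo (percentile 27.5).

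Both comparisons with the sibling library shared that library and therefore its chance values. xtr-miR-92b, dre-miR-125a and mmu-miR-6243 were among the 74 entries lower in both, and miR-135, miR-138 and miR-451 among the 40 higher in both. Independent lists of the same sizes would share 16.1 and 8.62 entries. Both comparisons use the same sibling counts and many entries share reads, so some excess over these numbers arises without any difference between conditions. Only 1 entry passed in opposite directions, xtr-miR-184. Among Xenopus entries 9 were lower and 6 higher in both, against 2.10 and 1.24 for independent lists. Across the 866 entries, which are not replicates, the log2 ratios had a Pearson r of 0.77 and a covariance of 1.30. Simulated counts with no difference between libraries gave r = 0.91 and a covariance of 0.235, from counting error in the shared library alone. Preparation effects in that library and reads shared between entries were not simulated. The rest of the covariance is therefore no measure of a difference common to both conditions. Across the Xenopus entries r was 0.63 and the covariance 0.745, against 0.92 and 0.169 simulated. Part of the overlap may come from the shared sibling library, which as 1 library cannot be split.

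**Figure D3:**
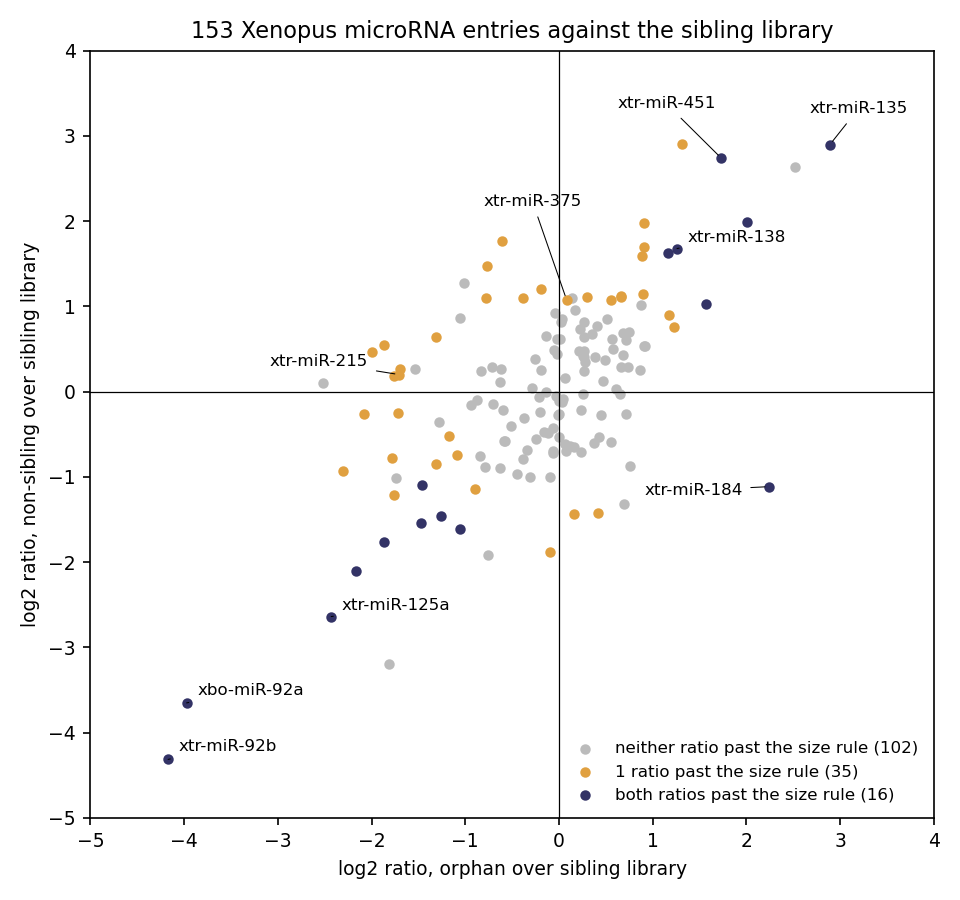
Log2 ratio of orphan over sibling (x axis) against log2 ratio of non-sibling over sibling (y axis) for 153 Xenopus microRNA entries, 1 point per entry and 1 library per condition, coloured by how many of both ratios passed the size rule. xtr-miR-92b lies lowest at -4.17 and -4.31, and xtr-miR-184 alone passed in opposite directions, at 2.24 and -1.11.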

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

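Every pattern and test weighed in this part was chosen after the ratios were seen. What would speak for or against the tests of depth and of the GC content of epithelial microRNAs was written down before they were run. All other tests were chosen only after the result was seen. Bootstrap intervals in this part resample related entries, which are not replicates. They describe the spread among entries and no uncertainty between samples, and for the gut and ciliated entries they are the range of the entries.

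Entries of plants and viruses, which enter only the alternative without a filter on low counts, held more than the 3 counts that a count of 0 allows in the orphan library (plants) and in the sibling library (plants and viruses). The 13 plant entries held 16 counts in the orphan library (0.710 unscaled CPM) and 16 in the sibling library (18.5 CPM), and none in the non-sibling library. The 2 viral entries held 5 counts in the sibling library (5.78 CPM), against 3 in the orphan and 1 in the non-sibling library.

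The sibling library stood apart through 74 entries at least 2-fold higher there than in both other libraries, among them xtr-miR-92b, mmu-miR-6243 and mmu-miR-5109. Thinning gave the number of entries that counting error at the sibling depth alone lets through the size rule. The full orphan library and itself thinned to the sibling total differed in 4.25 entries on average over 20 draws. The real orphan and sibling libraries differed in 211, of which the 74 are a part. Thinning keeps the make-up of a library and the rule allows for counting error, so a low number was built into this test. It speaks to counting error alone and not to where the 74 entries come from. Any other effect of a low yield stays open. Removing a linear GC trend fitted on all 153 Xenopus entries, the pattern entries included, took away part of the excess, not all of it. The median log2 excess of the 9 Xenopus entries that passed in both comparisons was 1.82 before and 1.34 (bootstrap interval 1.06 to 3.25) after. These 9 were picked for that excess and include xbo-miR-92a, xtr-miR-92a and xtr-miR-92b. Their median GC content was 54.5% against 43.2% for the others. Among those others the excess hardly followed GC content (r = 0.03). Removing their trend instead left the median of the 9 at 1.83 (bootstrap interval 1.40 to 3.83). The first fit holds the picked entries, and the second rests on entries of lower median GC content. Neither can exclude a GC bias of the sibling library. Fragments of other RNA counted under entries with no Xenopus family could account for at most 16 of the 74 entries, 21.6% against 5.89% of all entries used. Many of the other 58 entries are miR-92 under several species prefixes with shared reads. Shares of entries are thus no shares of distinct microRNAs, and this explanation may cover more of the pattern than 21.6%. Such fragments cannot be told apart from microRNAs here because no ribosomal or transfer RNA sequences of the frog were searched. A difference due to the sibling condition stays open and untested, as does any other property of this 1 library.

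With scaling on Xenopus entries alone, 6 of 9 gut, skin, miR-200 and miR-375 entries with at least 150 counts passed the size rule as higher in the non-sibling than in the orphan library, and the others lay in the same direction (log2 orphan over non-sibling -0.55 for xtr-miR-205a to -1.95 for xtr-miR-194). A smaller share of neural tissue in the non-sibling sample is argued against only where it would raise all other tissues alike. The muscle list had a median of 0.81 (bootstrap interval 0.31 to 1.60) in the opposite direction. Muscle values cannot speak to neural tissue replaced by epithelium alone, which stays open. The Xenopus entries of the neuronal list had a median of -0.14 in orphan over non-sibling (percentile 55.2), inside the range of random lists. A GC and length bias is argued against as the whole cause, since the median was -1.39 before and -1.50 (-1.95 to -0.88) after removal of that trend. Epithelial tissue in the non-sibling sample cannot be told apart from a shortage in the orphan sample: the 5 entries of the miR-34b and miR-449 families of ciliated cells had a median of -2.42 (-2.63 to -2.25), but against the sibling library these had 0.55 (0.10 to 1.77) in non-sibling and -1.87 (-2.52 to -0.61) in orphan, the 3 gut entries had a median of 0.20 (-0.25 to 0.64) in non-sibling and -1.71 (-1.72 to -1.31) in orphan, and the other 6 had 1.004 (0.33 to 1.15) in non-sibling and -0.11 (-0.54 to 0.05) in orphan. A difference due to rearing stays open and untested, and miR-375 and miR-200b among these entries were picked by the study on these libraries.

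miR-184 was 11.4 times as high in the orphan as in the non-sibling library. Reads of 1 sequence variant of the mature arm are argued against, since the other arm, ola-miR-184-5p, had a ratio of 5.41 (2.87 to 11.5). Cornea or lens tissue in the orphan sample could bring miR-184 together with miR-203, miR-204 and miR-205, whose Xenopus entries had a median log2 ratio of -0.55 but went both ways (-1.39 to 0.24), so this source cannot be told apart from a difference due to rearing, and both stay open.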

How the results depend on the processing

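No paired analysis was possible because each condition has 1 library. Scaling by DESeq2 size factors, leaving out the most abundant entry and, for orphan against non-sibling, TMM without the sibling library left all counts within 1.5 times of the values above. Of the named microRNAs, summed over all alternatives tried for them, 707 results kept their side of the size rule, 12 became weaker, 28 stronger (20 of them under total counts) and none reversed, where a change of sign in a ratio that did not pass the rule, such as that of xtr-miR-200b for orphan over sibling with the GC and length trend removed (-0.41), was not counted as a reversal. Xenopus entries alone, leaving out families that lack a Xenopus entry, thinning, quantile normalization, GC content and TMM without the sibling library were chosen after seeing the data. Where values moved and no reason is given, the cause was not tested.

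Against sibling, 77 entries were higher in orphan by the main rule. Total counts gave 121, a ratio of 1.5 167, a ratio of 4 11, an interval wholly beyond 2-fold 19 and quantile normalization 130. A sum of at least 150 counts gave 49, entries of 1 name summed 40, Xenopus entries 9 and thinning 44.5. These last settings tested fewer entries here and in the other comparisons, so their numbers are not directly comparable. The 134 lower entries became 77 with names summed, 23 among Xenopus entries and 68 at a ratio of 4. The 97 higher in non-sibling became 280 under total counts, 45 with names summed, 21 among Xenopus entries, 178 at a ratio of 1.5, 18 at a ratio of 4, 30 beyond 2-fold and 55.9 with thinning. The 104 lower became 57 under total counts, 14 among Xenopus entries, 188 at 1.5 and 35 at 4. Between orphan and non-sibling, the 65 higher became 30 under total counts, 100 with upper quartiles, 7 among Xenopus entries, 143 at 1.5, 17 at 4 and 43 beyond 2-fold. The 109 lower became 225 under total counts, 55 with names summed, 25 among Xenopus entries, 223 at 1.5 and 21 at 4.

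Of the list medians, 23 lay in the outer 2.5% of random lists at either end, and 11 did so among Xenopus entries, which are fewer. Under total counts 11 of 54 list medians changed sign, 10 of them inside the range of random lists. The other was the dopaminergic median for orphan over non-sibling, at -0.17 with its percentile unchanged (98.7). The reversals that follow are of medians outside that range. Without a filter the median for orphan over sibling was -0.060 (dopaminergic), -0.14 (neuronal) and -3.18 (erythrocyte), and that for non-sibling over sibling -2.88 (erythrocyte), where added entries with few or no counts enter. The erythrocyte median for non-sibling over sibling was -0.11 with names summed. The vascular median for orphan over sibling, 0.39 (percentile 98.8), was -0.025 at 150 counts, -0.17 among Xenopus entries, -0.052 with 5 counts added, -0.12 with family counts summed and -0.04 with members at 0 counts set to the floor, and the neuronal median was -0.15 with 5 counts added. The correlation of both ratios against sibling was 0.63 among Xenopus entries and 0.70 without families that lack a Xenopus entry. Depth limits the sibling library most. At its depth 1 count is 1.41 scaled CPM, and ratios on 3 or fewer sibling counts, such as those of miR-135, miR-451 and miR-155, have intervals spanning over 10-fold.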

Other observations

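All microRNAs named in this part, and the test in it, were chosen after their values were seen.

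Some microRNAs had similar levels in the sibling and non-sibling libraries and lower levels in the orphan library. xtr-miR-191 had 803 and 901 scaled CPM in the sibling and non-sibling libraries and 260 in the orphan library, at 0.323 times the sibling level (95% counting interval 0.296 to 0.353) and 0.288 times the non-sibling level (0.278 to 0.299). xtr-miR-425-5p, which shares a gene cluster with miR-191 in mammals, was at 0.338 times (0.290 to 0.396) and 0.284 times (0.266 to 0.302), and its ratio of non-sibling over sibling was 1.19 (1.02 to 1.39). xtr-miR-10c, of the Hox cluster list, behaved alike, at 0.261 times (0.186 to 0.376) and 0.312 times (0.265 to 0.368).

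Others stood lowest in the non-sibling library. xtr-miR-190 was 4.01 times as high in the orphan as in the non-sibling library (3.12 to 5.23), and the non-sibling level was 0.374 times the sibling level (0.222 to 0.659). xtr-miR-499, a muscle microRNA, gave 3.38 (2.74 to 4.21) and 0.369 (0.240 to 0.584). xtr-miR-204, abundant in the eye and choroid plexus of vertebrates, was highest in the sibling library, with 22043 scaled CPM against 12947 in the orphan and 9874 in the non-sibling library. xtr-miR-9a-3p, the other arm of the miR-9 precursor, was higher than in the sibling library in both orphan (2.54, 1.48 to 4.78) and non-sibling (3.17, 1.83 to 6.01), and xtr-miR-30a-5p was 2.56 times as high in orphan (2.30 to 2.85).

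A hypothesis from these data is that the ciliated-cell families miR-34b and miR-449 vary with the amount of epithelium in a sample. The 5 Xenopus entries were each lower in the orphan than in the non-sibling library, with a median log2 ratio of -2.42. By medians most of it was a low level in orphan (-1.87 against sibling, and 0.55 for non-sibling against sibling). For xtr-miR-449b-5p (-0.61 and 1.77, on 4 sibling counts) and xtr-miR-449c-5p (-0.77 and 1.48) most of it was a high level in non-sibling. Either pattern may reflect tissue composition or rearing, and 1 library per condition leaves both causes open. Repeated libraries per condition with in situ counts of ciliated cells on the dissected sections would test it, and it would fail if these families differed between conditions at equal epithelial area.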
